A study of Mus musculus with 27 samples.

How the data were processed

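Liver RNA of wild-type mice was measured by stranded mRNA sequencing in 27 libraries. Per the labels and the processing notes of the submitters, reads were aligned to the mouse genome mm10 (GRCm38) with STAR 2.4.0a, and reads per gene were counted with featureCounts 1.4.5-p1 from Subread. The deposited table holds a score for each gene and library, namely read counts that the authors divided by one scaling factor per library and rounded to whole numbers. The scaling method is not named in the notes. The median ratio of each library to the geometric mean of all libraries was 1.00 to 1.00, so the libraries were on a common scale, and low values were missing or doubled in the pattern that a scaling factor and rounding leave. The scaling factors and the depth per library were estimated from that pattern. On simulated tables the estimated factor was off by at most 5.27%. The table lists 45706 genes, of which 45143 identifiers (98.8%) matched the GENCODE M21 annotation of GRCm38 that gave the coordinates. The 37 mitochondrial genes in the table were at 0 in all libraries, so no mitochondrial share could be computed.

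Libraries were grouped by their titles into fasted, refed and caged food groups at 30, 60, 120 and 240 min, with 3 libraries each. For 2 libraries of 240 min the treatment label names the other group than the title. Their side was checked with a score, the mean over 200 genes of the log2 difference from the mean of the 6 libraries of 240 min, signed towards refed. The 200 genes were those of lowest p between refed and caged food livers at 120 min. The design text of the series speaks of 60 samples, and the samples beyond the 27 libraries were not analysed here. Replicate numbers were not taken to pair the libraries: over 108 pairs of libraries with the same number in different groups, the mean correlation of the residuals was -0.00944, and for 8 of 27 libraries the closest library of another group bore the same number.

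Genes with a value of at least 10 in at least 3 libraries were tested, which kept 15932 genes. The values were taken as log2 of the value plus 1, and limma 3.58.1 with a mean-variance trend in R 4.3.3 was fitted to the 9 group means of all 27 libraries, so that the spread was shared over the groups. The comparisons were refed against fasted, caged food against fasted and refed against caged food at each of 4 times, the same with equally weighted means over the times, and an F test of whether the difference between refed and caged food livers varied over time. P-values were adjusted by Benjamini-Hochberg over the genes tested within each comparison, and a gene was called at an adjusted p under 0.05. The 33 lists, 24 of gene groups and 9 of cell type markers with 662 distinct entries, were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. Members of a list were counted as risen or fallen over all genes tested and adjusted over the list alone. The responses to refeeding and caged food were compared by correlation across genes, beside 100 simulated draws of unchanged groups against a shared control group.

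The genes named for each comparison at a single time were the 5 largest rises and the 5 largest falls among called genes whose libraries did not overlap between the groups, with a mean of at least 50 in the higher group and without predicted genes, clones and sex-linked genes. To these came a fixed panel of genes of ER folding, glucose and lipid metabolism and the clock, and up to 4 members of lowest p for each list described. Of the genes that met these rules, 4 are not reported here. Except as follows, the groups, tests, lists, rule for named genes and alternatives were fixed before the data were examined. Alternatives without the libraries standing apart or with quality weights, and tests of explanations marked so below, were chosen afterwards.

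The test was checked on simulated data, for refed 120 min against fasted livers. Of genes changed 1.5, 2 and 4 times, 43.3%, 77.6% and 90.9% were called (29 of 67, 52 of 67 and 60 of 66). Among the 15725 genes tested, 14 genes without a change were called beside these. Of 50 simulated lists of 25 genes shifted by a log2 of 0.300, 50 were called, and 1 of 50 without a shift was. This need not hold for real lists (9 of 166 calls held with an estimated correlation). The alternatives were quantile normalization, a pseudocount of 5, no filter on low values, a replicate block, a fit of only the groups compared, each replicate left out in turn, and the 2 libraries with conflicting labels left out or grouped by the treatment label. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.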

Results

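Polyadenylated RNA from the livers of wild-type mice was sequenced in 27 libraries, which fall into 9 groups of 3. All mice had been fasted for 16 h. The fasted group served as the control, 4 groups had been refed for 30, 60, 120 or 240 min, and 4 groups had for the same times been given food in a small cage within their own cage, so that the food could be sensed and not eaten (caged food). The values were normalised read counts per gene. Their total per library was 40654573 to 50037562. The sequencing depth behind them, estimated from the spacing of the low values, was 25.6 to 52.4 M assigned reads per library (median 47.0 M), and 1 read corresponded to 0.775 to 1.69 normalised read counts. Between 19790 and 21068 genes were above 0 in each library. Libraries of the same group correlated across genes with Pearson's r between 0.979 and 0.991 on the log2 scale, where genes are not independent replicates.

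The number in parentheses after a gene's symbol below is its log2 fold change ± standard error from limma, with 3 libraries per group, and the p beside it is adjusted over all genes tested. Medians of lists are of the log2 fold changes of their genes, and counts of list members are out of those measured and over all genes tested unless said otherwise. For the largest changes named, all 3 libraries of one group lay beyond all 3 of the other. Counts and other calls use the adjusted p. The limma p-values rest on the spread within all 9 groups. Along the first principal component (18.3% of the variance) the refed libraries of 60 to 240 min lay between 19.0 and 49.4, and the fasted libraries between -17.9 and -15.4. The refed libraries of 30 min lay between -9.61 and -1.72. The caged food libraries lay between -25.9 and -10.5. Along the second component caged food 30 min replicate 1 (-35.7) and caged food 60 min replicate 2 (-35.9) stood apart from the other libraries of their groups, and caged food 120 min replicate 3 (-15.5) lay below replicates 1 and 2 (9.85 and 21.7). Refed 30 min replicate 1 held transcripts of pancreatic enzymes, with 554 normalised read counts of the elastase gene Cela2a against 15 and 12 in the other libraries of its group. The median of the pancreas markers lay above the fasted mean by 4.09 in caged food 30 min replicate 2, 2.46 in refed 120 min replicate 1 and 2.93 in refed 240 min replicate 1.

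**Figure D1:**
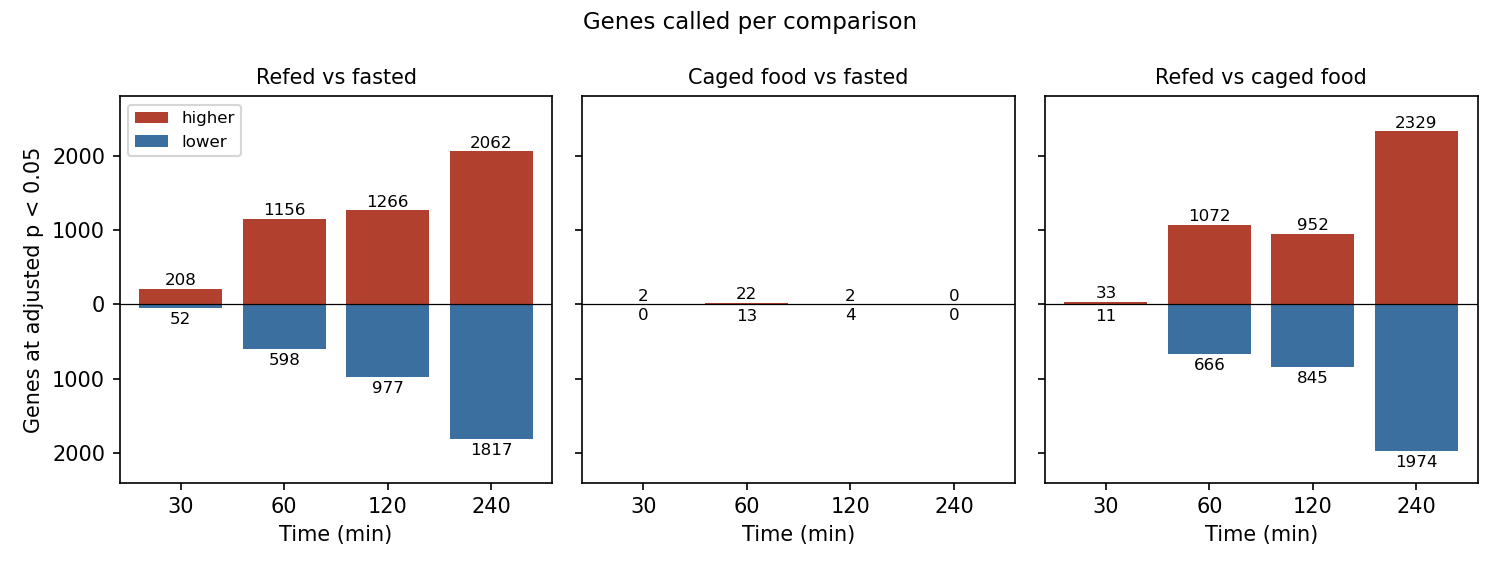
Number of genes past an adjusted p of 0.05 (limma, 3 libraries per group), by comparison and time in min, with genes that rose and genes that fell drawn separately. The count for refed against fasted went from 260 genes at 30 min to 3879 at 240 min, and caged food against fasted gave at most 35.

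Refed livers were compared with a fasted group not matched in time, so food and clock time were not separated. At 30 min, Nr4a1, an orphan nuclear receptor gene of the immediate early class (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795, plus strand of GRCm38), rose to 1228 ± 674 against 95.3 ± 1.15 normalised read counts (mean ± SD, n = 3 each; 3.50 ± 0.40, adjusted p = 1.77e-05). The largest other rises were those of Ckap2 and Ckap2l, which encode proteins of the mitotic spindle, of Cish, a suppressor of cytokine signalling, and of Hspa1b, an inducible heat shock protein. Reads of Hspa1b are not separable with certainty from those of its near-identical copy Hspa1a. Ckap2 rose by 3.17 ± 0.63, adjusted p = 0.00771, and Ckap2l by 3.11 ± 0.78, adjusted p = 0.0395. Cish rose by 3.10 ± 0.37, adjusted p = 2.72e-05, and Hspa1b by 3.05 ± 0.41, adjusted p = 1.38e-04. The largest falls were those of Arl4d (-1.66 ± 0.24, adjusted p = 2.77e-04) and the zinc finger repressor Snai2 (-1.51 ± 0.21, adjusted p = 2.11e-04). The kinase gene Pim1 (-1.33 ± 0.18, adjusted p = 1.83e-04), Efna1 (-1.23 ± 0.22, adjusted p = 0.00406) and the pro-apoptotic gene Bbc3 (-1.17 ± 0.17, adjusted p = 2.32e-04) fell as well.

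In all, 260 of 15932 genes passed limma, of which 208 rose and 52 fell. In the immediate early gene list, 7 of 28 genes rose and 0 fell, against 15 and 2 adjusted over the list alone. Immediate early genes had a median of 0.81 (camera adjusted p = 1.47e-14, or 0.00240 with an estimated correlation). Atf3 rose by 2.44 ± 0.27 and Jun by 2.12 ± 0.30. Cytosolic heat shock genes followed, where 6 of 17 genes rose, against 10 adjusted over the list alone. For heat shock genes the camera adjusted p was 1.34e-09 at a median of 0.39, or 0.326 with an estimated correlation. Dnajb1 rose by 1.17 ± 0.15 and Hsph1 by 1.38 ± 0.18. Of the cell cycle genes, 4 of 19 genes rose, against 10 adjusted over the list alone. By camera, cell cycle genes had a median of 0.99 and adjusted p = 1.67e-06, or 0.326 with an estimated correlation. Lowest in p was Cdc20 (3.03 ± 0.70). Of the glucose use and glycogen genes, Txnip fell by 0.57 ± 0.11, and the list as a whole was not called (median 0.0253, camera adjusted p = 0.756). Among ER chaperones and folding factors, 0 of 26 genes passed limma over all genes and 0 adjusted over the list alone (2 at an unadjusted p under 0.05). ER folding genes had a median of 0.10 (camera adjusted p = 0.0252, or 0.893 with an estimated correlation). PPAR-alpha targets were lower as a list, where 0 of 30 genes passed limma over all genes and 0 adjusted over the list alone (5 at an unadjusted p under 0.05). For PPAR-alpha target genes the camera adjusted p was 6.24e-06 at a median of -0.24, or 0.893 with an estimated correlation. In the acute phase list, 0 of 22 genes passed limma over all genes and 1 adjusted over the list alone (4 at an unadjusted p under 0.05). By camera, acute phase genes had a median of 0.28 and adjusted p = 0.00454, or 0.893 with an estimated correlation. For the pancreas markers, 0 of 10 genes passed limma over all genes and 0 adjusted over the list alone (1 at an unadjusted p under 0.05). Pancreas markers had a median of 2.46 (camera adjusted p = 0.00148, or 0.893 with an estimated correlation). Their median lay 8.21 above the fasted mean in replicate 1 against -0.0570 and -0.42 in replicates 2 and 3. Without the libraries that stood apart (refed 30 min replicate 1 in this comparison) the pancreas markers turned direction (median -0.34, camera adjusted p = 0.725), 194 genes were called and 0 of 19 cell cycle genes passed (median 0.56, camera adjusted p = 1.99e-04, or 0.593 with an estimated correlation). Kupffer cell markers (median 0.26, camera adjusted p = 0.0105, or 0.967 with an estimated correlation) were then higher and leukocyte markers (median -0.39, camera adjusted p = 0.0232, or 0.772 with an estimated correlation) lower, neither of which was called with all libraries (camera adjusted p = 0.108 and 0.154).

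The calls of Ckap2, Cdc20 and Ckap2l were lost without fasted replicate 3 (0.0642, 0.174 and 0.305), refed replicate 1 (0.0673, 0.149 and 0.213) or refed replicate 2 (0.0553, 0.123 and 0.1505), and that of Ckap2l also without fasted replicate 2 (0.0928), with a replicate block (0.0522), without the filter on low values (0.0762) and with only the groups compared (0.0581). The number of called genes was 127 without fasted replicate 2, 92 without fasted replicate 3, 159 without refed replicate 1 and 89 without refed replicate 2.

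At 60 min of refeeding, transcripts of glucose release fell. G6pc, which encodes the catalytic subunit of glucose-6-phosphatase, the last step of glucose release (ENSMUSG00000078650, chromosome 11, 101367561 to 101377903, plus strand), went from 17920 ± 3999.6 in fasted to 2380.3 ± 927 normalised read counts in refed livers (SD, n = 3 each; -2.96 ± 0.28, adjusted p = 4.19e-07). Igfbp1, an insulin-repressed binding protein for insulin-like growth factors (ENSMUSG00000020429, chromosome 11, 7197782 to 7202546, plus strand), fell by more (-3.80 ± 0.57, adjusted p = 7.32e-05). The other large falls were those of R3hdml (-2.58 ± 0.31, adjusted p = 5.44e-06), Arl4d (-2.46 ± 0.24, adjusted p = 4.87e-07) and Chac1, a glutathione-degrading enzyme induced by the transcription factor ATF4 (-2.16 ± 0.58, adjusted p = 0.0159). The largest rise was that of the serpin gene Serpina9 (ENSMUSG00000058260, chromosome 12, 103994743 to 104013755, minus strand), from 1.33 ± 1.53 to 162 ± 52.5 (6.30 ± 0.66, adjusted p = 1.38e-06). Serpina4-ps1, an annotated pseudogene with uncertain read assignment, rose by 4.46 ± 0.44, adjusted p = 6.64e-07. Hspa1b rose by 3.86 ± 0.41, adjusted p = 1.38e-06. Onecut1, a hepatocyte transcription factor also known as HNF6, rose by 3.29 ± 0.31, adjusted p = 4.19e-07.

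Altogether 1754 of 15932 genes passed limma, of which 1156 rose and 598 fell. Among gluconeogenesis and FOXO1 target genes, 10 of 24 genes fell and 2 rose, against 12 and 2 adjusted over the list alone. For gluconeogenesis genes the camera adjusted p was 8.11e-07 at a median of -0.47, or 0.0263 with an estimated correlation. Irs2, an insulin receptor substrate, changed by -2.15 ± 0.26, Klf15 by -0.93 ± 0.14 and Pck1 by -1.44 ± 0.26. Heat shock genes of the cytosol moved together, in that 14 of 17 genes rose, against 14 adjusted over the list alone. By camera, heat shock genes had a median of 0.88 and adjusted p = 3.88e-17, or 0.0806 with an estimated correlation. Hsph1, Bag3 and Dnajb1 rose by 2.14 ± 0.18, 1.54 ± 0.15 and 1.49 ± 0.15. In the ribosome biogenesis list, 19 of 35 genes rose, against 23 adjusted over the list alone. Ribosome biogenesis genes had a median of 0.43 (camera adjusted p = 2.77e-16, or 0.189 with an estimated correlation). Rrs1 had the lowest p (0.97 ± 0.10). ER chaperones and folding factors came next, where 6 of 26 genes rose, against 7 adjusted over the list alone. For ER folding genes the camera adjusted p was 0.00319 at a median of 0.21, or 0.880 with an estimated correlation. The transcription factor gene Xbp1, which drives ER chaperone expression, rose by 0.77 ± 0.11, Creld2 by 1.49 ± 0.33 and Hspa5, which encodes the chaperone BiP, by 0.94 ± 0.22, whereas Sdf2l1 stood at 0.98 ± 0.36, adjusted p = 0.0880. The ATF4 and integrated stress response list was split, since 2 of 23 genes rose and 4 fell, against 2 and 4 adjusted over the list alone. By camera, ATF4 and stress response genes had a median of -0.13 and adjusted p = 0.419. Atf3 (2.36 ± 0.27) and Ddit3 (1.65 ± 0.21) were higher, and Sesn2 (-1.84 ± 0.20) and Trib3 (-2.03 ± 0.28) were lower. Leukocyte markers were lower as a list, where 1 of 12 genes fell, against 2 adjusted over the list alone. Leukocyte markers had a median of -0.51 (camera adjusted p = 0.0430, or 0.880 with an estimated correlation). None of the libraries that stood apart is in these groups, so leaving them out cannot test this. The call of Chac1 was lost without fasted replicate 2 (adjusted p = 0.0545), fasted replicate 3 (0.0578) or refed replicate 1 (0.0732). The count of called genes was 1131 without fasted replicate 2 and 1155 without fasted replicate 3.

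**Figure D2:**
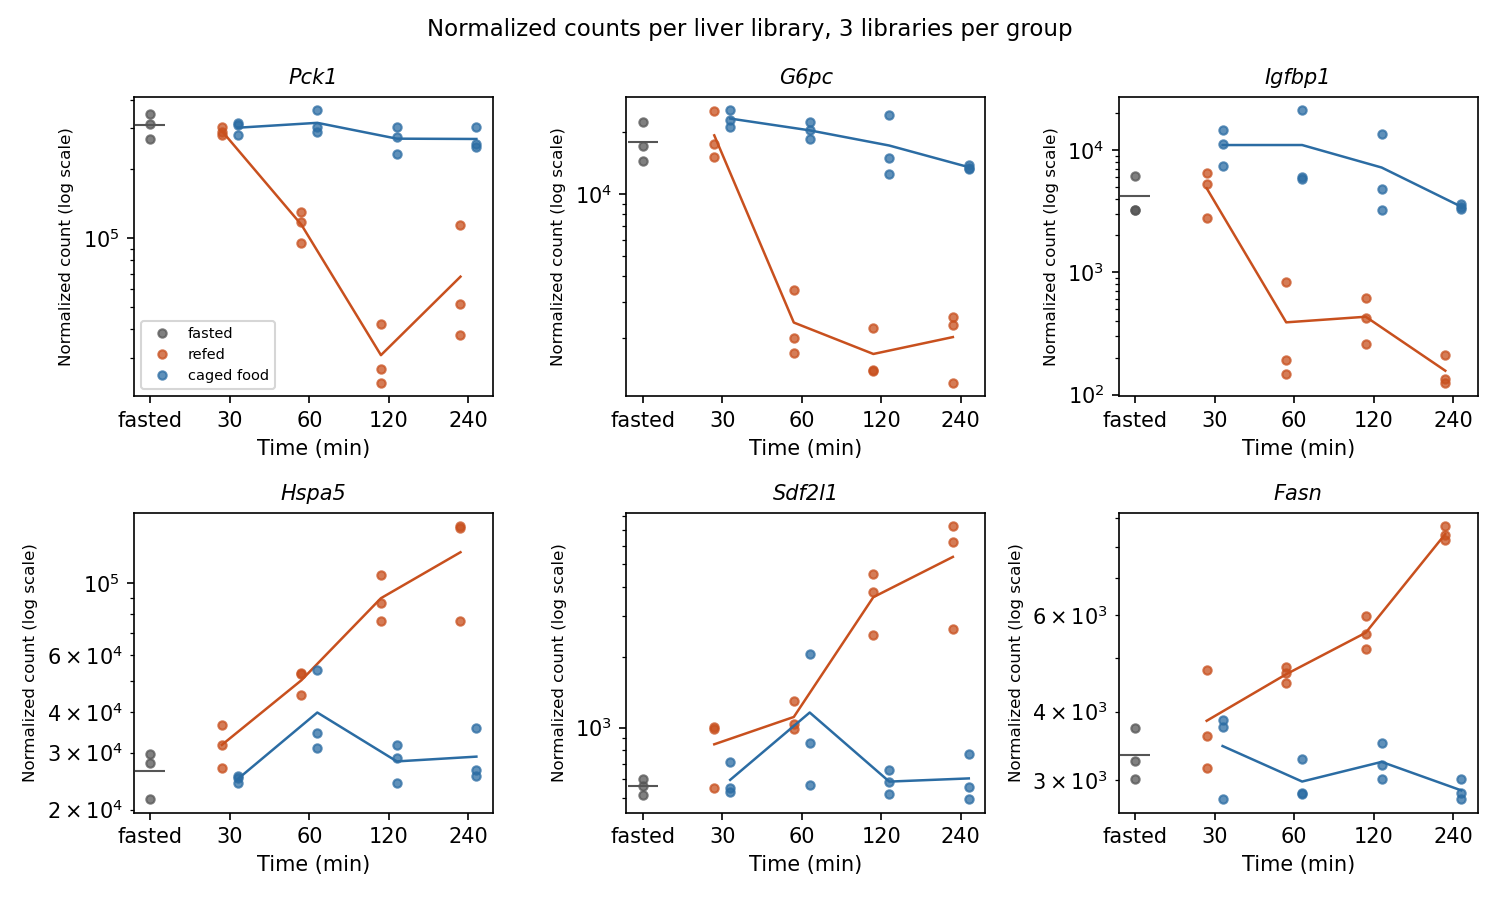
Normalised read counts (log axis) of Pck1, G6pc, Igfbp1, Hspa5, Sdf2l1 and Fasn in each library against time in min, for fasted, refed and caged food livers, with lines joining the group means of 3 libraries. At 240 min Hspa5 read 124301 in refed, 29140.3 in caged food and 26353 in fasted livers.

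At 120 min, genes of protein folding in the endoplasmic reticulum (ER) were higher in refed than in fasted livers. Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547, plus strand) rose to 89707 ± 15133 against 26353 ± 4242 normalised read counts (SD, n = 3 each; 1.77 ± 0.22, adjusted p = 8.31e-06), and Sdf2l1, an ER-resident folding factor (ENSMUSG00000022769, chromosome 16, 17130138 to 17132383, minus strand), rose to 3613 ± 1043 against 561 ± 46.1 (2.65 ± 0.36, adjusted p = 2.29e-05). The largest rise of all was that of Serpina9 (5.81 ± 0.66, adjusted p = 3.13e-06). Hspa1b (3.12 ± 0.41, adjusted p = 1.36e-05), Serpina4-ps1 (3.10 ± 0.44, adjusted p = 4.20e-05) and the prokineticin gene Prok1 (2.97 ± 0.46, adjusted p = 9.04e-05) rose as well. Mfsd2a, which encodes a transporter of lysophosphatidylcholine, fell the most (-3.75 ± 0.40, adjusted p = 1.60e-06). G6pc fell next (-3.43 ± 0.28, adjusted p = 2.46e-08), before the gluconeogenic enzyme gene Pck1 (-3.37 ± 0.26, adjusted p = 2.06e-08). Igfbp1 (-3.29 ± 0.57, adjusted p = 3.17e-04) and Angptl4, an inhibitor of lipoprotein lipase (-2.80 ± 0.22, adjusted p = 2.46e-08), fell as well.

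Over the whole table, 2243 of 15932 genes passed limma, of which 1266 rose and 977 fell. In the list of ER chaperones and folding factors, 18 of 26 genes rose, against 20 adjusted over the list alone. For ER folding genes the camera adjusted p was 3.06e-15 at a median of 0.66, or 0.147 with an estimated correlation. Hyou1, Manf and Creld2 rose by 1.96 ± 0.21, 2.22 ± 0.26 and 2.84 ± 0.33. For ER-associated degradation, 11 of 18 genes rose, against 12 adjusted over the list alone. By camera, ER-associated degradation genes had a median of 0.43 and adjusted p = 3.85e-08, or 0.147 with an estimated correlation. The ubiquitin ligase gene Syvn1 had the lowest p (1.84 ± 0.18). Of the ER translocation and COPII export genes, 20 of 34 genes rose, against 23 adjusted over the list alone. COPII and translocation genes had a median of 0.37 (camera adjusted p = 1.99e-13, or 0.147 with an estimated correlation). Sec23b had the lowest p (0.93 ± 0.11). Ribosome biogenesis genes were also higher, where 22 of 35 genes rose, against 29 adjusted over the list alone. For ribosome biogenesis genes the camera adjusted p was 6.50e-18 at a median of 0.47, or 0.136 with an estimated correlation. In the cytosolic heat shock list, 12 of 17 genes rose, against 13 adjusted over the list alone. By camera, heat shock genes had a median of 0.75 and adjusted p = 1.53e-13, or 0.136 with an estimated correlation. Gluconeogenesis and FOXO1 target genes moved the other way, since 14 of 24 genes fell and 1 rose, against 16 and 1 adjusted over the list alone. Gluconeogenesis genes had a median of -0.62 (camera adjusted p = 1.63e-09, or 0.00549 with an estimated correlation). Ppargc1a, a coactivator of gluconeogenesis, changed by -1.81 ± 0.22. Genes induced by glucocorticoids were lower, where 7 of 16 genes fell and 1 rose, against 8 and 1 adjusted over the list alone. For glucocorticoid-induced genes the camera adjusted p was 0.00271 at a median of -0.57, or 0.205 with an estimated correlation. Errfi1 (-1.55 ± 0.25) and Tat (-1.15 ± 0.22) fell. Cholesterol synthesis genes were higher, where 6 of 25 genes rose, against 6 adjusted over the list alone. By camera, cholesterol synthesis genes had a median of 0.19 and adjusted p = 0.00672, or 0.735 with an estimated correlation. Mvd rose by 2.10 ± 0.27 and Sqle by 1.72 ± 0.32. Without fasted replicate 2 the number of called genes was 1490.

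**Figure D3:**
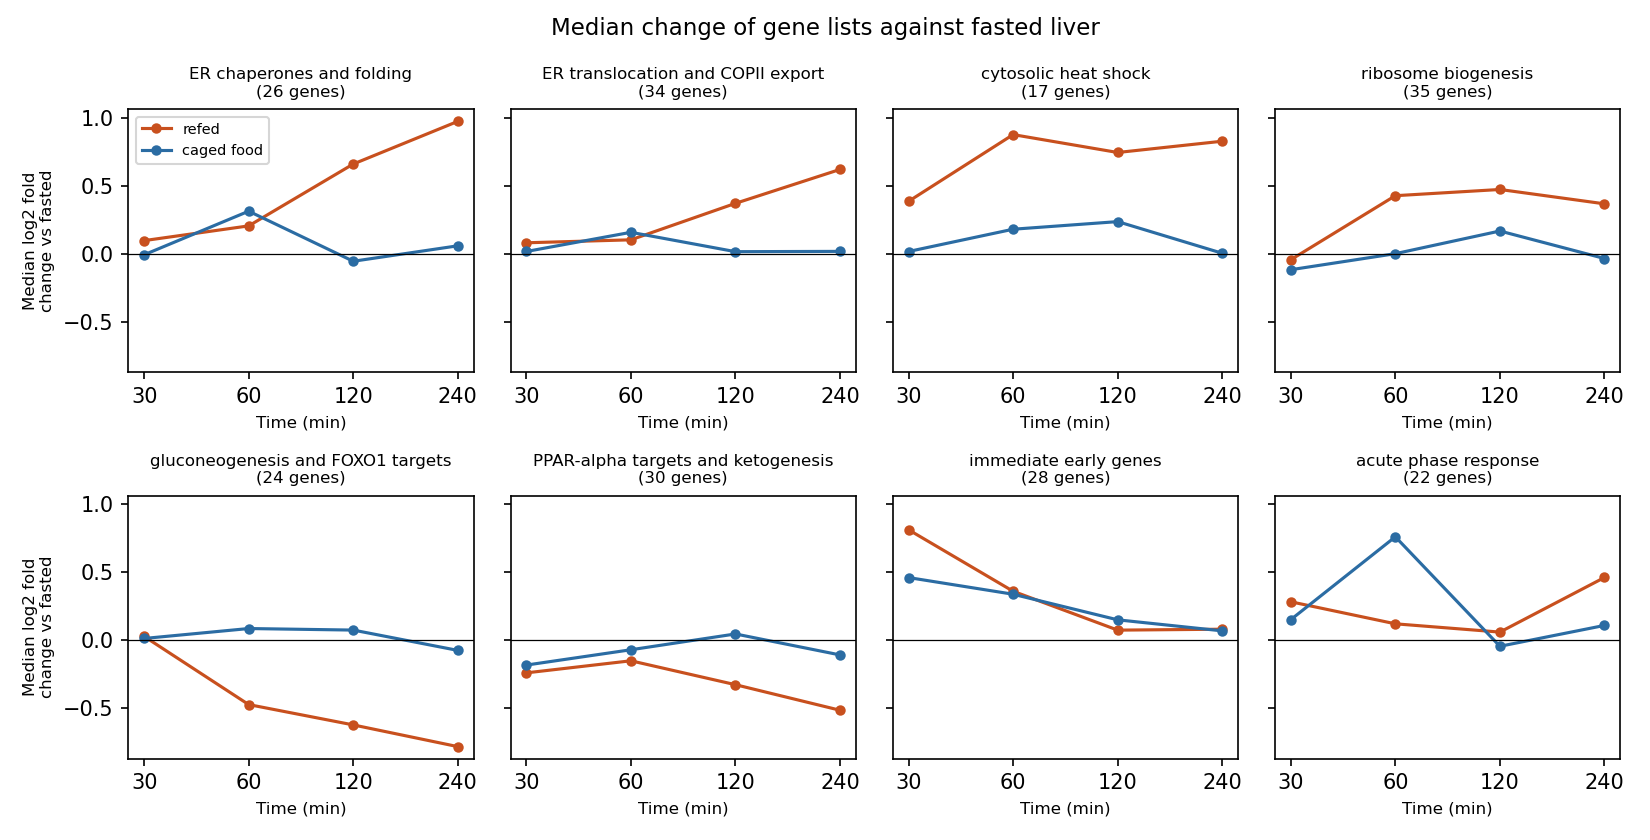
Median log2 fold change against fasted of 8 gene lists by time in min, for refed and for caged food livers (3 libraries per group). The median of the ER chaperones and folding list went from 0.10 at 30 min to 0.98 at 240 min of refeeding, and in caged food livers it was 0.31 at 60 min and 0.0600 at 240 min.

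After 240 min of refeeding, Igfbp1 showed the largest fall (-4.70 ± 0.57, adjusted p = 2.40e-06), followed by Angptl4 (-3.24 ± 0.22, adjusted p = 1.41e-09). G6pc (-3.19 ± 0.28, adjusted p = 3.21e-08), Mfsd2a (-3.01 ± 0.40, adjusted p = 9.46e-06) and the metallothionein gene Mt2 (-2.99 ± 0.37, adjusted p = 3.43e-06) came next. Serpina9 (6.45 ± 0.66, adjusted p = 2.54e-07) and Prok1 (4.29 ± 0.46, adjusted p = 3.84e-07) rose the most. Bhlha15, a transcription factor of secretory cells also known as Mist1, rose by 3.84 ± 0.55, adjusted p = 2.08e-05. The acute phase gene Saa2, whose reads are hard to separate from those of Saa1, rose by 3.64 ± 1.22, adjusted p = 0.0319, and Hapln1 by 3.46 ± 0.47, adjusted p = 1.03e-05. Hspa5 rose to 124301 ± 41480.3 against 26353 ± 4242 normalised read counts (SD, n = 3 each; 2.19 ± 0.22, adjusted p = 1.93e-07), with 76420 in replicate 3 against 149335 and 147147 in replicates 1 and 2. Fasn, which encodes fatty acid synthase, rose by 1.34 ± 0.12, adjusted p = 5.63e-08, and Cpt1a, the carnitine palmitoyltransferase of mitochondrial fatty acid uptake, fell by 1.11 ± 0.12 (adjusted p = 2.91e-07).

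Among all genes tested at 240 min, 3879 of 15932 genes passed limma, of which 2062 rose and 1817 fell. The ER lists were again higher. Of the ER chaperones and folding factors, 22 of 26 genes rose, against 23 adjusted over the list alone. ER folding genes had a median of 0.98 (camera adjusted p = 6.46e-18, or 0.122 with an estimated correlation). Of the COPII and translocation genes, 28 of 34 genes rose, against 29 adjusted over the list alone. For COPII and translocation genes the camera adjusted p was 8.85e-20 at a median of 0.62, or 0.101 with an estimated correlation. In the ER-associated degradation list, 13 of 18 genes rose, against 15 adjusted over the list alone. By camera, ER-associated degradation genes had a median of 0.53 and adjusted p = 2.90e-10, or 0.101 with an estimated correlation. PPAR-alpha targets and ketogenesis genes were lower, where 18 of 30 genes fell, against 23 adjusted over the list alone. PPAR-alpha target genes had a median of -0.52 (camera adjusted p = 1.36e-10, or 0.264 with an estimated correlation). Among gluconeogenesis and FOXO1 targets, 17 of 24 genes fell and 1 rose, against 18 and 2 adjusted over the list alone. For gluconeogenesis genes the camera adjusted p was 2.03e-09 at a median of -0.78, or 0.00632 with an estimated correlation. The transaminase gene Got1 (-1.62 ± 0.18) and Pck1 (-2.34 ± 0.26) fell. Amino acid catabolism and urea cycle genes were lower too, where 14 of 28 genes fell and 2 rose, against 16 and 2 adjusted over the list alone. By camera, amino acid catabolism genes had a median of -0.40 and adjusted p = 7.04e-06, or 0.167 with an estimated correlation. The amino acid transporter gene Slc38a4 had the lowest p (-1.06 ± 0.10). The fatty acid synthesis list was split, since 5 of 20 genes rose and 5 fell, against 8 and 5 adjusted over the list alone. Fatty acid synthesis genes had a median of 0.24 (camera adjusted p = 0.224). Elovl6 was higher (0.92 ± 0.15) and the desaturase gene Fads2 lower (-0.88 ± 0.12). In the acute phase list, 5 of 22 genes rose and 1 fell, against 5 and 1 adjusted over the list alone. For acute phase genes the camera adjusted p was 0.0256 at a median of 0.46, or 0.735 with an estimated correlation. Lowest in p was Apcs (1.64 ± 0.44).

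The call of Saa2 at 240 min was lost without fasted replicate 1 (adjusted p = 0.0622), 2 (0.0786) or 3 (0.0807) and without refed replicate 1 (0.0555) or 3 (0.158), with the conflicting libraries left out (0.169) and without the filter on low values (0.0565). Refed 240 min replicate 3 and caged food 240 min replicate 1 carry a treatment label that names the other group than their title, and grouping them by that label in place of the title left 0 called genes. Over the 200 genes with the lowest p between refed and caged food livers at 120 min, refed 240 min replicate 3 scored 0.497, next to 0.574 and 0.801 in refed replicates 2 and 1. Caged food replicate 1 scored -0.655, next to -0.635 and -0.582 in caged food replicates 2 and 3.

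**Figure D4:**
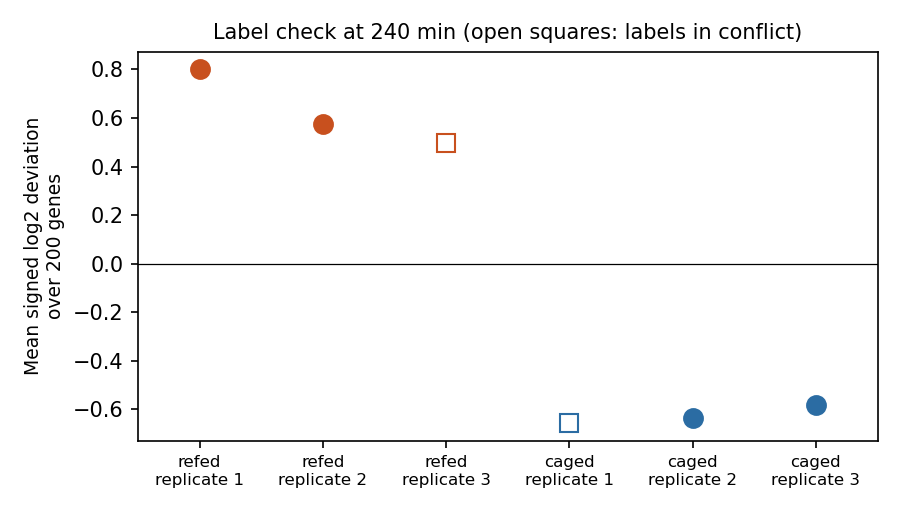
Score of each 240 min library over the 200 genes of lowest p between refed and caged food livers at 120 min (mean log2 difference from the mean of the 6 libraries, signed towards refed), with open squares for the libraries whose labels conflict. The 3 libraries titled refed lie between 0.497 and 0.801, and the 3 titled caged food between -0.655 and -0.582.

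Caged food livers were compared with the same fasted group, so sensed food, clock time and a longer fast were not separated. At 30 min, 2 of 15932 genes passed limma, of which 2 rose and 0 fell, and 1123 had an unadjusted p under 0.05. Stac3, which encodes an adaptor of excitation-contraction coupling known from muscle (ENSMUSG00000040287, chromosome 10, 127501686 to 127508823, plus strand), reached 63 ± 5.29 against 22.3 ± 3.51 normalised read counts (SD, n = 3 each; 1.46 ± 0.21, adjusted p = 0.00245). Ppp1r10, a nuclear regulatory subunit of protein phosphatase 1 (ENSMUSG00000039220, chromosome 17, 35916434 to 35932283, plus strand), reached 2610 ± 646 against 965 ± 209 (1.43 ± 0.18, adjusted p = 9.25e-04). Among immediate early genes, 0 of 28 genes passed limma over all genes and 6 adjusted over the list alone (14 at an unadjusted p under 0.05). By camera, immediate early genes had a median of 0.46 and adjusted p = 1.95e-07, or 0.0588 with an estimated correlation. Nr4a1 stood at 1.67 ± 0.40, adjusted p = 0.243. In the cell cycle list, 0 of 19 genes passed limma over all genes and 0 adjusted over the list alone (8 at an unadjusted p under 0.05). Cell cycle genes had a median of 0.60 (camera adjusted p = 9.58e-06, or 0.660 with an estimated correlation). Of the proteasome genes, 0 of 31 genes passed limma over all genes and 0 adjusted over the list alone (1 at an unadjusted p under 0.05). For proteasome genes the camera adjusted p was 5.78e-06 at a median of -0.13, or 0.819 with an estimated correlation. Without the libraries that stood apart, among which is caged food replicate 1, this list turned direction (median 0.0213, camera adjusted p = 0.673). With the spread estimated from the 6 libraries compared alone, Stac3 and Ppp1r10 had an adjusted p of 0.166 and 0.126. Without caged food replicate 2, where pancreas markers were higher, 5 genes were called.

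At 60 min of caged food, 35 of 15932 genes passed limma, of which 22 rose and 13 fell. Ip6k2, an inositol hexakisphosphate kinase gene (ENSMUSG00000032599, chromosome 9, 108783796 to 108806337, plus strand), rose to 4617 ± 883 against 1897 ± 437 normalised read counts (SD, n = 3 each; 1.29 ± 0.16, adjusted p = 4.50e-04). The interleukin-1 receptor gene Il1r1 rose by 1.15 ± 0.24, adjusted p = 0.0467. Herpud1, a membrane protein gene of ER-associated degradation (ENSMUSG00000031770, chromosome 8, 94386438 to 94395377, plus strand), rose by 1.12 ± 0.24, adjusted p = 0.0467. The p53-induced gene Trp53inp1 rose by 1.03 ± 0.22, adjusted p = 0.0486, and Fam25c by 0.88 ± 0.19, adjusted p = 0.0467. The largest fall was that of Vsig10l (-0.85 ± 0.16, adjusted p = 0.0258). Sowahb (-0.81 ± 0.16, adjusted p = 0.0366), the Wnt coactivator gene Bcl9 (-0.76 ± 0.10, adjusted p = 8.50e-04) and Plekhg6 (-0.64 ± 0.11, adjusted p = 0.0211) fell too. Of the ER chaperones and folding factors, 0 of 26 genes passed limma over all genes and 0 adjusted over the list alone (11 at an unadjusted p under 0.05). As a list they were higher (median 0.31, camera adjusted p = 4.55e-10, or 0.410 with an estimated correlation), with Hspa5 at 0.57 ± 0.22, adjusted p = 0.359, and Sdf2l1 at 0.84 ± 0.36, adjusted p = 0.417. In the COPII and translocation list, 0 of 34 genes passed limma over all genes and 3 adjusted over the list alone (11 at an unadjusted p under 0.05). By camera, COPII and translocation genes had a median of 0.16 and adjusted p = 2.07e-09, or 0.368 with an estimated correlation. For ER-associated degradation, 1 of 18 genes rose, against 5 adjusted over the list alone. ER-associated degradation genes had a median of 0.19 (camera adjusted p = 1.89e-06, or 0.277 with an estimated correlation). The called member was Herpud1.

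Caged food 60 min replicate 2 stood out in some of these lists. Its median over the ER chaperones and folding list lay 0.52 above the fasted mean, against 0.18 and 0.16 in replicates 1 and 3, and without it the list stood lower (median 0.15, camera adjusted p = 0.00240, or 0.628 with an estimated correlation). The COPII and translocation list (median 0.11, camera adjusted p = 2.15e-04, or 0.438 with an estimated correlation) and the ER-associated degradation list (median 0.18, camera adjusted p = 5.60e-04, or 0.438 with an estimated correlation) moved less without it. Acute phase genes were higher as a list, where 1 of 22 genes rose, against 17 adjusted over the list alone. For acute phase genes the camera adjusted p was 6.67e-14 at a median of 0.76, or 0.277 with an estimated correlation. Their median lay 1.84 above the fasted mean in replicate 2 and 0.27 and 0.17 in replicates 1 and 3. Saa1, whose reads are hard to separate from those of Saa2, read 92023 normalised counts in replicate 2 and 1200 and 2946 in the other libraries of the group. In the glucocorticoid-induced list, 0 of 16 genes passed limma over all genes and 4 adjusted over the list alone (5 at an unadjusted p under 0.05). By camera, glucocorticoid-induced genes had a median of 0.53 and adjusted p = 3.95e-04, or 0.277 with an estimated correlation. The heat shock list likewise held no called gene, where 0 of 17 genes passed limma over all genes and 6 adjusted over the list alone (6 at an unadjusted p under 0.05). Heat shock genes had a median of 0.18 (camera adjusted p = 3.04e-05, or 0.460 with an estimated correlation). Without replicate 2 the heat shock list was higher (median 0.28, camera adjusted p = 3.01e-04, or 0.438 with an estimated correlation). The acute phase list (median 0.24, camera adjusted p = 0.00291, or 0.438 with an estimated correlation) and the glucocorticoid list (median 0.32, camera adjusted p = 5.89e-04, or 0.438 with an estimated correlation) stayed past the threshold without it with the preset correlation. Cell type markers moved as well. For Kupffer cell markers, 0 of 12 genes passed limma over all genes and 0 adjusted over the list alone (0 at an unadjusted p under 0.05). For Kupffer cell markers the camera adjusted p was 0.00439 at a median of 0.34, or 0.726 with an estimated correlation. Without replicate 2 they were not called (median -0.11, camera adjusted p = 0.301), while erythroid (median 0.69, camera adjusted p = 5.89e-04) and hepatocyte markers (median 0.18, camera adjusted p = 0.0234) were higher. Stellate cell and fibroblast markers (median -0.32, camera adjusted p = 0.00116) and leukocyte markers (median -0.45, camera adjusted p = 0.0218) were lower without it, and each of these 4 lists had an adjusted p of 0.438 with an estimated correlation.

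Several of these 60 min calls were lost when any of several single libraries was left out. Those of Il1r1, Trp53inp1 and Sowahb were lost without fasted replicate 1 (adjusted p from 0.0514 to 0.0733). Calls of Il1r1, Herpud1, Trp53inp1, Fam25c, Vsig10l, Sowahb and Plekhg6 were lost without fasted replicate 2 (adjusted p from 0.102 to 0.178) or 3 (0.127 to 0.301). The same genes lost their calls without caged food replicate 1 (adjusted p from 0.0609 to 0.113). Without caged food replicate 2 the losses were Il1r1, Herpud1, Trp53inp1, Fam25c and Sowahb (adjusted p from 0.0784 to 0.185). Without caged food replicate 3 they were Herpud1, Trp53inp1, Fam25c, Vsig10l and Plekhg6 (adjusted p from 0.0571 to 0.120). The number of called genes was 5 and 2 without fasted replicates 2 and 3 and 15, 10 and 16 without caged food replicates 1, 2 and 3, and 0 with the spread estimated from the 6 libraries compared alone, where Ip6k2 had an adjusted p of 0.115 and Bcl9 of 0.115.

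At 120 min of caged food, 6 of 15932 genes passed limma, of which 2 rose and 4 fell, with 1226 genes at an unadjusted p under 0.05. The GTPase-activating protein gene Tbc1d8 (1.27 ± 0.21, adjusted p = 0.0140) and the transcription factor gene Arid3a (1.08 ± 0.19, adjusted p = 0.0312) rose. The aryl hydrocarbon receptor gene Ahr fell to 1777 ± 61.5 against 2801 ± 246 normalised read counts (SD, n = 3 each; -0.65 ± 0.11, adjusted p = 0.0140), as did Sipa1l2 (-1.26 ± 0.19, adjusted p = 0.0105), the pseudogene Nlrp5-ps (-1.19 ± 0.22, adjusted p = 0.0482) and Lrch1 (-0.57 ± 0.10, adjusted p = 0.0312). In the ribosome biogenesis list, 0 of 35 genes passed limma over all genes and 5 adjusted over the list alone (12 at an unadjusted p under 0.05). By camera, ribosome biogenesis genes had a median of 0.17 and adjusted p = 1.00e-09, or 0.655 with an estimated correlation. Cytosolic heat shock genes were higher as a list, where 0 of 17 genes passed limma over all genes and 1 adjusted over the list alone (4 at an unadjusted p under 0.05). Heat shock genes had a median of 0.24 (camera adjusted p = 7.13e-04, or 0.943 with an estimated correlation). For the bile acid metabolism list, 0 of 17 genes passed limma over all genes and 0 adjusted over the list alone (2 at an unadjusted p under 0.05). For bile acid genes the camera adjusted p was 0.0424 at a median of -0.15, or 0.655 with an estimated correlation. Calls were lost without fasted replicate 1 for Arid3a, Nlrp5-ps and Lrch1 (adjusted p from 0.0522 to 0.149), without fasted replicate 2 for Tbc1d8, Arid3a, Sipa1l2, Nlrp5-ps, Ahr and Lrch1 (adjusted p from 0.0960 to 0.286), without fasted replicate 3 for Tbc1d8, Arid3a, Nlrp5-ps, Ahr and Lrch1 (adjusted p from 0.0558 to 0.175), without caged food replicate 1 for Nlrp5-ps and Lrch1 (adjusted p from 0.0907 to 0.168), without replicate 2 for Arid3a, Nlrp5-ps and Lrch1 (adjusted p from 0.0529 to 0.117) and without replicate 3 for Tbc1d8, Arid3a, Sipa1l2, Nlrp5-ps, Ahr and Lrch1 (adjusted p from 0.128 to 0.217). The count was 0 without fasted replicate 2, 1 without fasted replicate 3 and 0 without caged food replicate 3, and with only the groups compared it was 0, all 6 calls being lost (adjusted p from 0.0550 to 0.166), while Nlrp5-ps was also lost with a replicate block (0.0779), quantile normalization (0.0828), a pseudocount of 5 (0.0503) or no filter (0.103) and Arid3a with quantile normalization (0.0770).

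At 240 min of caged food, 0 of 15932 genes passed limma, and 752 had an unadjusted p under 0.05. The 3 libraries of each group did not overlap for 13.8% of the genes, where chance gives 10%. The panel genes with large changes after refeeding were near their fasted levels, with G6pc at -0.38 ± 0.28, adjusted p = 0.995, Igfbp1 at -0.22 ± 0.57, adjusted p = 0.996, and Hspa5 at 0.14 ± 0.22, adjusted p = 0.996. No list was called, and the lowest camera adjusted p was 0.430. Of the ER chaperones and folding factors, 0 of 26 genes passed limma over all genes and 0 adjusted over the list alone (0 at an unadjusted p under 0.05). By camera, ER folding genes had a median of 0.0600 and adjusted p = 0.430.

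The direct comparisons of refed with caged food livers of the same time asked what eating adds to sensing food. At 30 min, 44 of 15932 genes passed limma, of which 33 rose and 11 fell. The rises of refed over caged food livers were led by Hspa1b (2.12 ± 0.41, adjusted p = 0.0170) and Nr4a1 (1.83 ± 0.40, adjusted p = 0.0486). Cish (1.78 ± 0.37, adjusted p = 0.0309), Atf3 (1.54 ± 0.27, adjusted p = 0.0102) and Gapdh (1.41 ± 0.17, adjusted p = 7.10e-05) rose too. Gapdh encodes a glycolytic enzyme and has many pseudogenes, so the assignment of its reads is uncertain. Arl4d (-1.95 ± 0.24, adjusted p = 8.77e-05) and Efna1 (-1.04 ± 0.22, adjusted p = 0.0417) led the falls. Snai2 (-0.99 ± 0.21, adjusted p = 0.0400) and Bbc3 (-0.93 ± 0.17, adjusted p = 0.0102) fell too. In the cytosolic heat shock list, 4 of 17 genes rose, against 7 adjusted over the list alone. Heat shock genes had a median of 0.23 (camera adjusted p = 2.64e-09, or 0.484 with an estimated correlation). Lowest in p was Hsph1 (1.05 ± 0.18). Of the immediate early genes, 3 of 28 genes rose, against 8 adjusted over the list alone. For immediate early genes the camera adjusted p was 8.21e-05 at a median of 0.20, or 0.341 with an estimated correlation. The leukocyte markers were lower as a list, where 0 of 12 genes passed limma over all genes and 0 adjusted over the list alone (1 at an unadjusted p under 0.05). By camera, leukocyte markers had a median of -0.56 and adjusted p = 0.00383, or 0.867 with an estimated correlation. Calls were lost without refed replicate 1 for Hspa1b, Cish, Efna1 and Snai2 (adjusted p from 0.0849 to 0.117), replicate 2 for Hspa1b, Nr4a1, Cish, Atf3, Efna1, Snai2, Bbc3 and Hsph1 (adjusted p from 0.0528 to 0.309) and replicate 3 for Nr4a1, Cish, Atf3, Efna1, Snai2 and Bbc3 (adjusted p from 0.0506 to 0.318), and without caged food replicate 1 for Hspa1b, Nr4a1, Efna1 and Snai2 (adjusted p from 0.167 to 0.268), replicate 2 for Nr4a1, Cish, Efna1, Snai2 and Bbc3 (adjusted p from 0.0516 to 0.143) and replicate 3 for Nr4a1, Atf3, Efna1 and Bbc3 (adjusted p from 0.0590 to 0.123). The count was 8 without refed replicate 2, 15 without refed replicate 3, 25 and 21 without caged food replicates 1 and 3, and 19 without the libraries that stood apart, among which is caged food replicate 1.

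At 60 min, refed livers differed from caged food livers by 1072 genes that were higher and 666 that were lower by limma, out of 15932. Serpina9 (5.36 ± 0.66, adjusted p = 8.33e-06) and Serpina4-ps1 (4.65 ± 0.44, adjusted p = 2.00e-07) were higher in refed livers. So were Onecut1 (4.27 ± 0.31, adjusted p = 9.24e-09) and Cish (3.91 ± 0.37, adjusted p = 1.52e-07). Igfbp1 fell to 389 ± 383 against 10964 ± 8816 normalised read counts (SD, n = 3 each; -4.97 ± 0.57, adjusted p = 2.97e-06). Chac1 (-3.20 ± 0.58, adjusted p = 6.39e-04), G6pc (-3.16 ± 0.28, adjusted p = 6.63e-08), Angptl4 (-2.85 ± 0.22, adjusted p = 2.82e-08) and Irs2 (-2.82 ± 0.26, adjusted p = 1.10e-07) were lower as well. Among gluconeogenesis and FOXO1 targets, 9 of 24 genes fell, against 12 adjusted over the list alone. Gluconeogenesis genes had a median of -0.44 (camera adjusted p = 1.46e-08, or 0.00849 with an estimated correlation). In the ribosome biogenesis list, 18 of 35 genes rose, against 20 adjusted over the list alone. For ribosome biogenesis genes the camera adjusted p was 9.53e-15 at a median of 0.40, or 0.234 with an estimated correlation. Nop56 had the lowest p (1.33 ± 0.13). ER chaperones and folding factors were not called between these groups, where 1 of 26 genes rose and 1 fell, against 1 and 1 adjusted over the list alone. By camera, ER folding genes had a median of -0.11 and adjusted p = 0.486. Hspa5 stood at 0.37 ± 0.22, adjusted p = 0.328, and Sdf2l1 at 0.14 ± 0.36, adjusted p = 0.862, while Xbp1 was higher by 0.55 ± 0.11, adjusted p = 0.00132. Acute phase genes were lower in refed livers, where 4 of 22 genes fell, against 8 adjusted over the list alone. Acute phase genes had a median of -0.89 (camera adjusted p = 7.90e-06, or 0.614 with an estimated correlation). Without the libraries that stood apart, among which is caged food replicate 2, this list was no longer called (median -0.16, camera adjusted p = 0.281). Kupffer cell markers were lower too, where 1 of 12 genes fell, against 1 adjusted over the list alone. For Kupffer cell markers the camera adjusted p was 0.0155 at a median of -0.36, or 0.761 with an estimated correlation. Of the leukocyte markers, 1 of 12 genes fell, against 1 adjusted over the list alone. By camera, leukocyte markers had a median of -0.67 and adjusted p = 0.0155, or 0.761 with an estimated correlation. Without the libraries that stood apart neither was called (camera adjusted p = 0.971 and 0.512), and the median of the Kupffer cell markers was 0.0251. The acute phase gene Il1r1 fell by 1.03 ± 0.24 (adjusted p = 0.00661), and without caged food replicate 2 its log2 fold change was -0.67 (adjusted p = 0.0569). The call of Xbp1 was lost with the spread estimated from the 6 libraries compared alone (adjusted p = 0.101), where 465 genes were called.

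At 120 min, the ER folding genes were higher in refed than in caged food livers, Hspa5 with 89707 ± 15133 against 28171 ± 3799.9 normalised read counts (SD, n = 3 each; 1.67 ± 0.22, adjusted p = 1.83e-05) and Sdf2l1 with 3613 ± 1043 against 587 ± 69.0 (2.58 ± 0.36, adjusted p = 3.75e-05). Altogether 1797 of 15932 genes passed limma, of which 952 rose and 845 fell. Among the largest rises was that of Serpina9 (3.38 ± 0.66, adjusted p = 0.00143). The steroid dehydrogenase gene Hsd3b5 (2.82 ± 0.46, adjusted p = 2.40e-04), the ER-associated degradation gene Derl3 (2.80 ± 0.75, adjusted p = 0.0156) and Hspa1b (2.65 ± 0.41, adjusted p = 1.13e-04) rose too. Mfsd2a (-4.06 ± 0.40, adjusted p = 4.58e-07) and Igfbp1 (-3.86 ± 0.57, adjusted p = 7.10e-05) led the falls. G6pc (-3.34 ± 0.28, adjusted p = 3.79e-08), Pck1 (-3.17 ± 0.26, adjusted p = 3.79e-08) and Angptl4 (-2.99 ± 0.22, adjusted p = 7.22e-09) followed. In the list of ER chaperones and folding factors, 19 of 26 genes rose, against 21 adjusted over the list alone. ER folding genes had a median of 0.74 (camera adjusted p = 3.86e-19, or 0.135 with an estimated correlation). For COPII export and translocation, 20 of 34 genes rose, against 23 adjusted over the list alone. For COPII and translocation genes the camera adjusted p was 3.96e-14 at a median of 0.37, or 0.135 with an estimated correlation. For ER-associated degradation, 11 of 18 genes rose and 0 fell, against 12 and 1 adjusted over the list alone. By camera, ER-associated degradation genes had a median of 0.33 and adjusted p = 2.76e-07, or 0.135 with an estimated correlation. Gluconeogenesis and FOXO1 targets were lower, where 15 of 24 genes fell and 0 rose, against 19 and 1 adjusted over the list alone. Gluconeogenesis genes had a median of -0.78 (camera adjusted p = 9.33e-14, or 5.58e-04 with an estimated correlation). Glucocorticoid-induced genes were lower, where 7 of 16 genes fell and 1 rose, against 11 and 1 adjusted over the list alone. For glucocorticoid-induced genes the camera adjusted p was 4.50e-06 at a median of -0.85, or 0.135 with an estimated correlation. Mt2 had the lowest p (-2.46 ± 0.37). Genes of amino acid catabolism and the urea cycle were lower, where 11 of 28 genes fell and 2 rose, against 17 and 2 adjusted over the list alone. By camera, amino acid catabolism genes had a median of -0.42 and adjusted p = 1.93e-08, or 0.135 with an estimated correlation. Sinusoidal endothelial markers were lower as a list, where 1 of 12 genes fell, against 1 adjusted over the list alone. Sinusoidal endothelial markers had a median of -0.15 (camera adjusted p = 0.0487, or 0.349 with an estimated correlation). The call of this gene, Oit3, was lost without any 1 of the 6 libraries (adjusted p from 0.0582 to 0.161). The call of Derl3 was lost without refed replicate 2 (adjusted p = 0.0976), refed replicate 3 (0.0538) or caged food replicate 3 (0.0548), and without refed replicate 2 the count was 1111.

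Between refed and caged food livers at 240 min, 4303 of 15932 genes passed limma, of which 2329 rose and 1974 fell. Serpina9 was higher in refed livers (6.26 ± 0.66, adjusted p = 3.28e-07), as was Moxd1, which encodes a relative of dopamine beta-hydroxylase (4.28 ± 1.42, adjusted p = 0.0270). Prok1 (3.64 ± 0.46, adjusted p = 2.89e-06) and Hsd3b5 (3.20 ± 0.46, adjusted p = 1.71e-05) were higher too. Igfbp1 (-4.48 ± 0.57, adjusted p = 3.47e-06) and Mt2 (-4.13 ± 0.37, adjusted p = 3.62e-08) led the falls. Mfsd2a (-3.18 ± 0.40, adjusted p = 3.58e-06), the pro-apoptotic gene Bmf (-3.15 ± 0.35, adjusted p = 5.51e-07) and Angptl4 (-3.11 ± 0.22, adjusted p = 2.37e-09) followed. Fasn rose to 8431 ± 253 against 2875 ± 122 normalised read counts (SD, n = 3 each; 1.55 ± 0.12, adjusted p = 7.24e-09). Of the COPII export and translocation genes, 28 of 34 genes rose, against 30 adjusted over the list alone. For COPII and translocation genes the camera adjusted p was 1.38e-17 at a median of 0.64, or 0.119 with an estimated correlation. Of the ER chaperones and folding factors, 22 of 26 genes rose, against 23 adjusted over the list alone. By camera, ER folding genes had a median of 0.84 and adjusted p = 5.52e-15, or 0.163 with an estimated correlation. In the ribosome biogenesis list, 29 of 35 genes rose and 1 fell, against 31 and 1 adjusted over the list alone. Ribosome biogenesis genes had a median of 0.44 (camera adjusted p = 2.07e-13, or 0.163 with an estimated correlation). Interferon response genes were higher, where 10 of 19 genes rose, against 11 adjusted over the list alone. For interferon response genes the camera adjusted p was 1.13e-04 at a median of 0.62, or 0.469 with an estimated correlation. Irgm1 had the lowest p (0.80 ± 0.14). NRF2 targets were higher, where 6 of 13 genes rose, against 7 adjusted over the list alone. By camera, NRF2 target genes had a median of 0.44 and adjusted p = 0.00304, or 0.163 with an estimated correlation. The oxidative stress gene Osgin1 had the lowest p (2.26 ± 0.28). No cell type marker list was called, and the lowest camera adjusted p was 0.0527 for sinusoidal endothelial markers (median -0.17), of which 4 of 12 genes fell. Of the stellate cell and fibroblast markers 2 of 12 genes fell, and of the cholangiocyte markers 2 of 7 rose, as many as adjusted over the list alone. Calls were lost with the conflicting libraries left out for Oit3, Kdr, Fcgr2b, Bmp2, Lum, Sox9 and Moxd1 (adjusted p from 0.0606 to 0.119), without refed replicate 1 for Bmp2, Hand2 and Krt19 (adjusted p from 0.0973 to 0.237), replicate 2 for Lum, Hand2, Sox9, Krt19 and Moxd1 (adjusted p from 0.0597 to 0.156) and replicate 3 for Oit3 (adjusted p = 0.0537), and without caged food replicate 1 for Bmp2, Lum, Hand2 and Moxd1 (adjusted p from 0.0736 to 0.0874), replicate 2 for Hand2, Sox9, Krt19 and Moxd1 (adjusted p from 0.0601 to 0.113) and replicate 3 for Krt19 (adjusted p = 0.167). Grouping by the treatment label in place of the title left 1 called gene in this comparison.

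Averaged over the 4 times, 2382 of 15932 genes passed limma, of which 1429 rose and 953 fell between refed and fasted livers. In the cytosolic heat shock list, 14 of 17 genes rose, against 14 adjusted over the list alone (median 0.78, camera adjusted p = 1.46e-15, or 0.112 with an estimated correlation), and among gluconeogenesis and FOXO1 targets, 12 of 24 genes fell and 2 rose, against 15 and 3 adjusted over the list alone (median -0.55, camera adjusted p = 9.87e-09, or 0.00919 with an estimated correlation). Between caged food and fasted livers, 0 genes passed limma and 645 had an unadjusted p under 0.05. The immediate early genes were higher in caged food livers as a list, where 0 of 28 genes passed limma over all genes and 0 adjusted over the list alone (6 at an unadjusted p under 0.05). Immediate early genes had a median of 0.20 (camera adjusted p = 3.68e-05, or 0.220 with an estimated correlation). Between refed and caged food livers, 4990 of 15932 genes passed limma, of which 2750 rose and 2240 fell. For ribosome biogenesis, 30 of 35 genes rose and 1 fell, against 31 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 3.14e-15, or 0.171 with an estimated correlation). At all 4 times of refeeding, 55 genes rose against fasted, among them Hsph1, Atf3, Serpina9 and Onecut1, and 14 fell, among them Arl4d, Bbc3, Txnip and Ip6k2. Of the 1266 genes that rose at 120 min, 1013 also rose at 240 min, and of the 977 that fell, 761 also fell. Both comparisons share the fasted libraries, and the overlap from these alone was not computed. The count for refed livers against fasted was 1550, 1255 and 1219 without fasted replicates 1, 2 and 3, and that for caged food livers was 1 without fasted replicate 1.

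The difference between refed and caged food livers varied over the 4 times for 1588 of 15932 genes (limma F test), and 3868 had an unadjusted p under 0.05. For Hspa5 the log2 difference of refed minus caged food livers was 0.34, 0.37, 1.67 and 2.04 at 30, 60, 120 and 240 min (adjusted p = 6.80e-04 for the variation over time). For Sdf2l1 it was 0.47, 0.14, 2.58 and 3.04 (adjusted p = 5.94e-04), for Fasn 0.15, 0.65, 0.78 and 1.55 (adjusted p = 1.26e-04), for Pck1 -0.0460, -1.48, -3.17 and -2.15 (adjusted p = 8.40e-05) and for G6pc -0.30, -3.16, -3.34 and -2.81 (adjusted p = 6.07e-05). The count was 755, 974 and 1057 without refed replicate 1, 2 or 3 of every time and 891 and 1044 without caged food replicate 1 or 2 of every time, and 43 with the 240 min libraries grouped by the treatment label.

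The responses to refeeding and to caged food, each against the same 3 fasted libraries, were compared across the 15932 genes tested, which are not independent replicates. Pearson's r of the log2 fold changes was 0.602 at 30 min, 0.337 at 60 min, 0.408 at 120 min and 0.208 at 240 min. Simulated unchanged groups against 1 shared control gave a mean r of 0.530 (-0.236 to 0.788 over 100 draws). This wide range holds all 4 observed values and excludes no shared response. At 30 min, both genes that rose with caged food, Ppp1r10 and Stac3, also rose with refeeding. The overlap from the shared fasted libraries alone was not computed. At 60 min, 5 genes rose in both comparisons (Ccdc117, Ints6, Kansl1, Prdm2 and Rbm12b2) and 8 fell in both, Bcl9 among them. Ip6k2 and Cln8 were among 3 genes that rose with caged food and fell with refeeding at 60 min. At 120 min, Arid3a rose and Lrch1 fell in both comparisons, and Ahr fell with caged food and rose with refeeding. The genes in these overlaps were named after their values were seen.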

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

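The tests of the conflicting labels, of replicate 2 behind the ER list at 60 min of caged food and of the explanations for the missing calls in caged food livers were chosen only after the result was seen, and the test of the scaling and the regroupings were written before.

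The difference between refed and caged food livers varied over the 4 times for 1588 genes by a limma F test of the difference itself. Of the panel genes, the adjusted p of this test was 6.80e-04 for Hspa5, 5.94e-04 for Sdf2l1, 0.00178 for Dnajb9 and 0.0254 for Ddit3. For the metabolic genes it was 1.26e-04 for Fasn, 8.40e-05 for Pck1, 6.07e-05 for G6pc, 0.0113 for Igfbp1, 0.00166 for Irs2 and 1.87e-04 for Cpt1a, and for the clock gene Per1 it was 0.0155.

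In 2 libraries of 240 min the title and the treatment label name different groups. Caged food replicate 1 scored -0.655 over the 200 genes of the label check, on the side of the caged food libraries without a conflict (-0.635 and -0.582), and refed replicate 3 scored 0.497, next to 0.574 and 0.801. Both values argue against a wrong title and leave a wrong treatment label as a candidate explanation. A biological explanation was not tested.

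The ER chaperones and folding list was higher in caged food livers at 60 min than in fasted livers (median log2 fold change 0.31, camera adjusted p = 4.55e-10, adjusted p = 0.410 with an estimated correlation). With quantile normalization the median was 0.209, which argues against the scaling of the libraries as the cause. Without caged food replicate 2 it was 0.149 (camera adjusted p = 0.00240, adjusted p = 0.628 with an estimated correlation), just under the bound set for excluding that this library alone made the difference, although the medians of the other libraries (0.18 and 0.16) lay above the highest fasted library (0.0770). A response to sensed food and the contribution of that library therefore cannot be told apart for this list.

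No gene was called for caged food livers as the mean of 4 times against fasted, and 2382 were for refed livers. A wider spread among caged food libraries could hide calls, but the median SD within groups was 0.196 against 0.180 on the log2 scale, a ratio of 1.09. The 2382 refed calls at the same group sizes are part of the pattern, so they cannot show that small effects would pass. Without the 2 libraries standing apart 0 genes were called. Effects of caged food too small for this test stay open, as does an absence of effects averaged over time, and both are hypotheses.

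For the comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. The real and the highest other count were 260 and 0 for refed 30 min against fasted, 1754 and 0 for refed 60 min against fasted, 2243 and 0 for refed 120 min against fasted, 3879 and 0 for refed 240 min against fasted. For caged food against fasted they were 2 and 0 at 30 min, 35 and 0 at 60 min, 6 and 0 at 120 min, 0 and 0 at 240 min, and at 240 min all 10 splits gave 0. For refed against caged food they were 44 and 0 at 30 min, 1738 and 1 at 60 min, 1797 and 1 at 120 min, 4303 and 1 at 240 min. Of 100 regroupings, the real one included, 1 gave as many genes as refed against caged food over all times (4990, others 2993 at most). This argues against chance. Against fasted 1 did (2382, others 2312 at most), but mixing times leaves chance open. For the variation over time, 2 of 100 did (1588 genes, with 3561 in the highest other). Regrouping also breaks differences constant over time, so this share cannot exclude chance. For caged food against fasted over all times the real count was 0, which all 100 groupings reach by necessity, so their number says nothing about chance. The highest other count, 1275, could come from a structure of the samples, which was not tested.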

How the results depend on the processing

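The alternatives with library weights or without the libraries standing apart were chosen after seeing the data, as tests added to the others. Where a value differed below, the cause was not tested unless it is named. Of 558 calls of named genes, 527 stayed past the threshold with quantile normalization, 557 with a pseudocount of 5, 504 without a filter on low values, 482 with only the groups compared, 536 with a replicate block and 540 with library weights. With the conflicting libraries left out 187 stayed and 21 were lost, and with the libraries standing apart left out 86 stayed and 37 were lost. Grouped by the treatment label, 0 stayed and 208 were lost. Leaving out single replicates lost a call in 469 of the fits and kept it in 2879. Of 166 list calls, 9 held with an estimated correlation, 157 with a replicate block and 67 of those involving 240 min with the conflicting libraries left out, while 19 were lost without the libraries standing apart and 8 by the treatment label.

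With library weights the counts rose by over 1.5 times in 8 results: 759 for refed 30 min against fasted, 4520 at 120 min, 67 and 121 for caged food 30 and 120 min against fasted, 88 and 3303 for refed against caged food at 30 and 120 min, 4240 for the refed mean against fasted and 2741 for the variation over time. Refed against caged food at 60 min fell to 1347, and caged food at 60 min, with 40, no longer had the most genes of the caged food times. With only the groups compared, refed 30, 120 and 240 min against fasted rose to 371, 2682 and 4463, and counts fell by over 1.5 times to 1153 for refed 60 min against fasted, 1, 0 and 0 for caged food at 30, 60 and 120 min, and 20 and 465 for refed against caged food at 30 and 60 min. For caged food 60 min against fasted the count was 19 with quantile normalization, 14 without a filter, 20 with a replicate block and 14 without the libraries standing apart. Without the latter, refed against caged food at 30 min gave 19. For caged food 240 min the count was 1 without a filter, 1 by the treatment label and 1 without the conflicting libraries.

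Grouped by the treatment label, which moves a refed and a caged food library between the groups, the counts were 0 for refed 240 min against fasted, 1 for refed against caged food at 240 min, 247 for the refed mean against fasted, 1656 for the refed mean against the caged food mean and 43 for the variation over time. Without the libraries standing apart, 4 lists turned direction: pancreas markers at refed 30 min (camera adjusted p = 0.725), the proteasome at caged food 30 min (0.673) and Kupffer cell markers at caged food 60 min (0.308) and in refed against caged food at 60 min (0.971). Spearman's rho in place of Pearson's r for the shared response was 0.522 at 30 min and 0.136 at 240 min.

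Leaving out each replicate in turn, the counts for refed against fasted ranged over 89 to 200 at 30 min, 1131 to 1553 at 60 min, 1490 to 1838 at 120 min and 2587 to 3395 at 240 min. For caged food against fasted they ranged over 2 to 5, 2 to 34, 0 to 9 and 0 to 0, and for refed against caged food over 8 to 31, 1204 to 1700, 1111 to 1504 and 3040 to 4009. For the means they ranged over 1219 to 2182 for refed against fasted, 0 to 1 for caged food against fasted and 3956 to 4607 for refed against caged food, and over 755 to 1152 for the variation over time. The shared response had a Pearson's r of 0.514 to 0.672, 0.263 to 0.444, 0.358 to 0.496 and 0.148 to 0.301 at the 4 times. A count-based test was not run, since the values are scaled and rounded and whole reads were not recovered for every library. At the depth and group size at hand, the simulated data showed that changes of 1.5 times were mostly missed (43.3% called).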

Other observations

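No hypothesis was tested here, and the tests are those chosen before. After 240 min of refeeding, further gene groups differed from fasted livers. In the interferon response list, 8 of 19 genes rose, against 9 adjusted over the list alone. Interferon response genes had a median of 0.58 (camera adjusted p = 0.00142, or 0.579 with an estimated correlation). The GTPase genes Irgm1 (0.73 ± 0.14) and Igtp (1.05 ± 0.21) rose. Of the NRF2 targets, 6 of 13 genes rose, against 7 adjusted over the list alone. For NRF2 targets the camera adjusted p was 0.00142 at a median of 0.50, or 0.122 with an estimated correlation. Gstm3 rose by 1.89 ± 0.25. For the proteasome, 4 of 31 genes rose, against 2 adjusted over the list alone. By camera, proteasome genes had a median of 0.16 and adjusted p = 0.00413, or 0.735 with an estimated correlation. The calls of Psmc2 and Psma4 were lost without any 1 fasted replicate (adjusted p from 0.0544 to 0.159) or without refed replicate 1 or 2 (0.111 to 0.195). In the phospholipid synthesis list, 9 of 21 genes fell and 2 rose, against 9 and 2 adjusted over the list alone. Phospholipid synthesis had a median of -0.11 (camera adjusted p = 0.0151, or 0.360 with an estimated correlation). Lpin2 (-2.12 ± 0.17) and Lpcat3 (-1.19 ± 0.10) fell. Per2 (1.72 ± 0.29) was higher and Per1 (-1.72 ± 0.37) lower. Of the oxidative phosphorylation genes, 1 of 35 genes fell, against 0 adjusted over the list alone. For oxidative phosphorylation genes the camera adjusted p was 0.0233 at a median of -0.0836, or 0.786 with an estimated correlation. Cox4i1 was lost without fasted replicate 3 (0.0523), refed replicate 3 (0.0697) or both conflicting libraries (0.0810).

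Cell type markers differed too. Of the sinusoidal endothelial markers, 2 of 12 genes fell, against 1 adjusted over the list alone. By camera, sinusoidal endothelial markers had a median of -0.22 and adjusted p = 0.0138, or 0.294 with an estimated correlation. Kdr was lost without any library but fasted replicate 2 (adjusted p from 0.0512 to 0.215), and Oit3 (0.0523) and Kdr (0.134) with the conflicting libraries left out. Of the stellate cell and fibroblast markers, 3 of 12 genes fell, against 3 adjusted over the list alone. Stellate cell and fibroblast markers had a median of -0.36 (camera adjusted p = 0.0615). All 3 (Hand2, Ecm1 and Reln) were lost without fasted replicate 1 (adjusted p from 0.0608 to 0.152), fasted replicate 2 (0.0555 to 0.0770) or refed replicate 1 (0.0756 to 0.152), and Ecm1 and Reln without fasted replicate 3 (0.140 and 0.0988) or refed replicate 2 (0.152 and 0.138), and Ecm1 without refed replicate 3 (0.0506). Hepatocyte, Kupffer cell, cholangiocyte, leukocyte and erythroid markers were not called (camera adjusted p = 0.726, 0.682, 0.553, 0.726 and 0.726).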
